A study of Homo sapiens with 6 samples.

How the data were processed

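RNA sequencing of NK92, an established human NK cell line, was analysed in 6 libraries, 3 of untreated cells and 3 of cells given 1000 nM SAHA for 24 h. Per the labels, cells at 12 passages were grown with 100 U/ml of interleukin 2, the RNA was polyadenylated, though their extraction text names removal of ribosomal RNA beside oligo dT selection, libraries were made with the NEBNext Ultra kit with 9 cycles of PCR, and sequencing was paired-end. The submitters' processing notes name STAR 2.6.0a, RSEM (no version), deepTools 3.5.1 and the build hg19, with no settings for strandedness or filters. Each library has its own table of 57820 gene models with versioned Ensembl identifiers and symbols. Per the file headers, the authors give an expected count for each gene, the RSEM estimate of its fragments, which is not a whole number for every gene and has a different total in each library. The deposited TPM values are transcript abundances scaled by effective length and library, and have the same total in each library. The deposited FPKM values were looked at and not used.

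The groups were taken from the labels, and the replicate numbers were not used as pairs, since the labels state no pairing and the libraries of equal number were not alike beyond their group. Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with default settings (14070 genes kept, holding 99.9% of the counts), TMM factors (mean 0.968 in the controls and 1.03 with SAHA), and the robust quasi-likelihood test of SAHA against control. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a false discovery rate of 0.05, and all tests were two-sided. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common dispersion was 0.00305, a biological coefficient of variation of 5.52%. Totals of 18675093 to 26178112 counts set the precision of each gene, and binomial intervals cover the sampling of genes only, while the limit for olfactory receptor genes is a t limit from the spread between libraries. Values per library (detected genes, shares) were compared by exact permutation tests.

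In total 34 gene lists were fixed, for the cell line, the drug class, RNA quality and other cell types, and the 31 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. TRBC1, CD24 and PECAM1 were not matched to a gene model. The named genes followed a rule. It took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 TPM in the higher group and groups fully apart, leaving out clone, noncoding, pseudogene and mitochondrial names. It also took the 2 called genes of smallest adjusted p in each list and a set of genes named whatever their result. Some genes of the lists are not reported here. The rule, the lists, the tests and the alternatives were chosen before the data were examined, except where the text says otherwise.

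Alternatives were other scalings (RLE, upper quartile, library size only), no filter and a stricter filter (5 CPM in at least 3 libraries), a replicate block, each library left out, limma-trend on log2 TPM with 1 or 0.1 added, DESeq2 1.42.0, limma voom, a false discovery rate of 0.01, and a test against a fold change of 1.5. A correction of each library for GC content and gene length was chosen after seeing the data. It used GC content from GENCODE 29 transcripts, matched by identifier for 96.3% of the tested genes, and lengths from the tables. Since that annotation is on another build, no positions are given. Genes whose reads are shared with close copies, such as the KIR, KLRC, HLA and histone genes and HSPA1A and HSPA1B, hold counts as RSEM divided them. The edgeR test was tested on simulated data of the same depth. The spread of each gene past the filter was set to its trend with expression, without scatter of genes around that trend. There, 82.1% of genes moved 1.5-fold, 85.1% of genes moved 2-fold and 98.5% of genes moved 4-fold were called, all in the right direction. Of the calls, 4.32% were genes that had not been moved, a share that data with such scatter may exceed. The genes moved were 67, 67 and 66, with 14017 tested, far fewer than the genes called in the data. In the list test on simulated data, no list was called without a change, and the single list lowered by 1.5-fold was called. Genes were drawn independently of each other there, so this cannot show the false list calls that correlation between genes may give. Tables and figures were made with R and Python 3.11.15.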

Results

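The series measured RNA, given in the labels as polyadenylated, in NK92, an established human natural killer (NK) cell line that grows in interleukin 2. There were 3 libraries of untreated cells (control) and 3 of cells given 1000 nM SAHA for 24 h, described by the labels as biological replicates. SAHA (vorinostat) is an inhibitor of the zinc-dependent histone deacetylases. Expected counts summed to 24785861, 24336720 and 25165309 in the controls and to 18675093, 26178112 and 26085124 in the SAHA libraries. Pearson correlations of log2 CPM (counts scaled to the library total) lay between 0.991 and 0.993 within a group and between 0.971 and 0.974 across groups. The first principal component held 68.1% of the variance. A control library had 12836 ± 65.6 genes at 1 TPM (transcript abundance scaled for length and library) or more, and a SAHA library 13265 ± 86.0 (SD, n = 3 per group). The difference of 429 genes had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. The 10 most abundant genes held 5.48 ± 0.0108% of the counts in the controls and 5.45 ± 0.151% with SAHA (exact permutation p = 1). Genes of the mitochondrial DNA held 4.32 ± 0.186% in the controls and 4.74 ± 0.128% with SAHA (exact permutation p = 0.1).

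The comparison asks which genes change expression when NK cells meet an inhibitor of histone deacetylases. The controls are labelled untreated, so any effect of a solvent or of handling the treated cultures cannot be told apart from that of SAHA. In SAHA-treated NK92 cells, transcripts of GZMB and of the chemokine CCL5 were higher, and those of DNAJB1 and UNC13D were lower. GZMB, the granule protease granzyme B, rose 2.24-fold, from 544 ± 27.8 to 1293 ± 43.3 TPM, and CCL5 rose 2.56-fold, from 849.85 ± 36.7 to 2335 ± 117 TPM. DNAJB1, a co-chaperone of heat shock proteins, was 8.76-fold lower, at 321 ± 9.09 TPM in the controls and 40.75 ± 0.707 TPM with SAHA. UNC13D, which primes lytic granules for release, was 4.73-fold lower. Fold changes compare TMM-scaled counts, TPM values are group means ± SD, and n = 3 libraries per group throughout.

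Of 14070 tested genes, 8420 (59.8%) changed at a false discovery rate of 0.05 in edgeR, 4272 of them higher and 4148 lower with SAHA. Another 5650 did not pass. Changes of at least 1 on the log2 scale were reached by 851 higher and 390 lower genes. From the quartile of lowest mean expression to that of highest, these were 532 and 199, 228 and 70, 56 and 63, and 35 and 58, so that the excess of higher genes lies in the 2 quartiles of lower expression. The 3 libraries of a group lay fully apart from the other 3 in 65.0% of the tested genes, where chance gives 10%. The median log2 fold change of all tested genes was 0.01 with TMM scaling and 0.11 with scaling to library size only. With the latter, 62.1% of the called genes were higher, against 50.7% with TMM. With a correction for GC content and length added after seeing the data it was 42.4%, 3836 higher and 5208 lower. The median log2 fold change was then -0.05, so part of this tilt is a shift of all genes, as another scaling gives. Small changes near the middle thus depend on these choices.

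**Figure D1:**
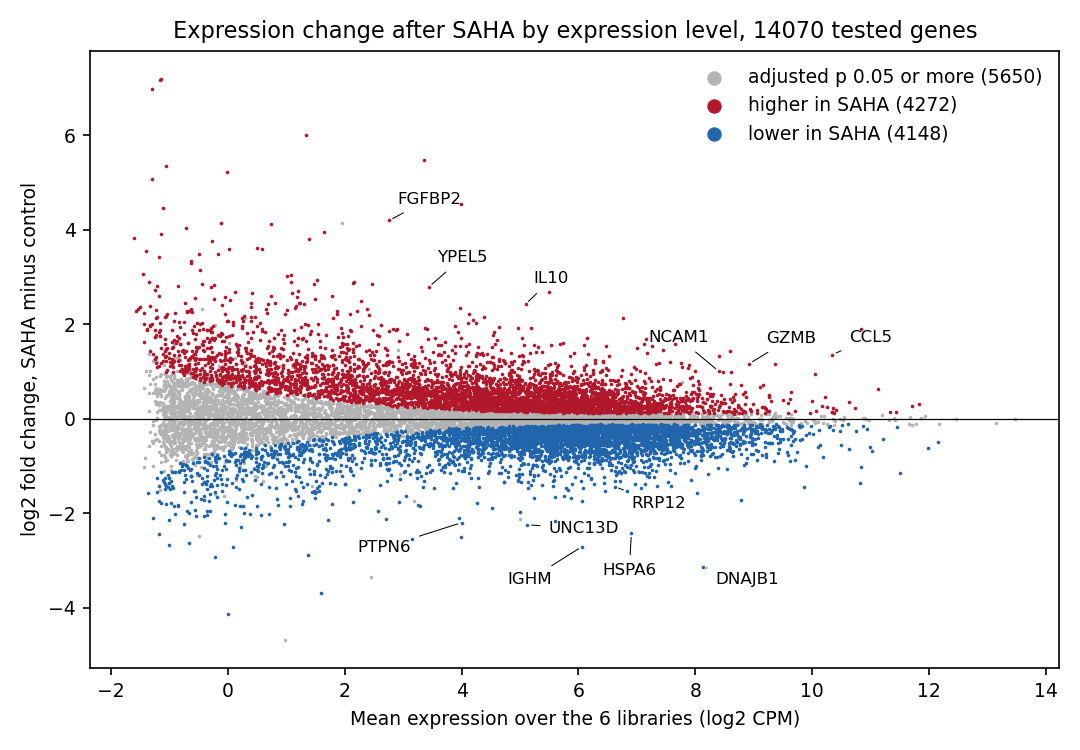
Log2 fold change (SAHA minus control, vertical axis) against mean expression over the 6 libraries (log2 CPM, horizontal axis). Each point is a tested gene, red for the 4272 higher and blue for the 4148 lower with SAHA at a false discovery rate of 0.05, grey for the 5650 that did not pass. Genes at least 2-fold higher outnumber those at least 2-fold lower overall (851 and 390), but not in the quartile of highest expression (35 and 58).

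Among the abundant genes with the largest rises was FGFBP2 (ENSG00000137441.7), which codes for a secreted protein of cytotoxic lymphocytes. It rose by 4.20 ± 0.18 on the log2 scale (SE), from 0.917 ± 0.292 to 18.4 ± 1.58 TPM, with an adjusted p of 6.62e-12. IL10 (ENSG00000136634.5), a cytokine that restrains inflammation, rose 5.37-fold, from 11.1 ± 1.54 to 62.4 ± 3.91 TPM. YPEL5 rose 6.90-fold, PACSIN1, an adaptor in endocytosis, 5.11-fold, and HMGN5, a nucleosome-binding protein, 4.64-fold. IGHV1OR15-1, an immunoglobulin variable segment, rose 5.50-fold and GATS 4.56-fold. IGHV1OR15-1 had few reads, 7, 7 and 13 in the controls and 40, 52 and 61 with SAHA. FOXD1, a forkhead transcription factor, had the largest rise of these in counts, 5.48 ± 0.91 on the log2 scale, or 6.52 without control 2. It was at 1.25 ± 1.13 TPM in the controls and 14.7 ± 7.68 TPM with SAHA, a log2 ratio of 3.56 that lies below the rise in counts, RSEM's length for it being 645 ± 111 and 2039 ± 72.1 bases. Its adjusted p of 0.00713 became 0.0728 in limma voom.

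The largest falls included chaperones and immunoglobulin heavy chains. DNAJB1 (ENSG00000132002.3) fell by 3.13 on the log2 scale (SE 0.06, adjusted p = 2.31e-16), and HSPA6, an inducible member of the heat shock protein 70 family, was 5.35-fold lower. IGHM (ENSG00000211899.3), the immunoglobulin mu heavy chain, was 6.50-fold lower, at 120.5 ± 0.433 TPM in the controls and 20.0 ± 1.44 TPM with SAHA. IGHG3 was 4.34-fold lower. PTPN6, a phosphatase recruited by inhibitory receptors, was 4.58-fold lower, at 54.8 ± 2.71 and 14.2 ± 2.71 TPM. TRPM2, a calcium-permeable channel, was 4.45-fold lower and DDN 5.69-fold lower.

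Gene lists fixed for this cell line and drug class were tested with limma camera, and 8 of 31 passed at an adjusted p of 0.05, 5 higher and 3 lower with SAHA. None passed with a correlation estimated within each list, where 2 of 31 had an unadjusted p under 0.05. With the directional test of fry, which does not compare a list with other genes, 24 lists passed. Members that are named below because their group holds 5 or fewer genes, and that the rule for named genes does not hold, were chosen after their values were seen.

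The list of cytotoxic granule, granule release and death ligand genes rose, with 13 of 20 tested members higher and 4 lower (adjusted p = 0.0133; adjusted p = 0.522 with an estimated correlation). The counts were 13 and 4 adjusted over the list alone. Beside GZMB, the pore-forming PRF1 rose 1.65-fold, from 246 ± 8.40 to 439 ± 31.9 TPM. The 4 lower members were UNC13D, GZMM, CTSW and CST7. Transcription factors of NK development rose as a list, with 19 of 25 higher and 2 lower, or 20 and 3 adjusted over the list alone (adjusted p = 0.000114; adjusted p = 0.282 with an estimated correlation). EOMES, a T-box factor of NK maturation, rose 1.45-fold and RUNX2 1.91-fold. TBX21, the related T-box factor, was at 101 ± 2.57 TPM in the controls and 104 ± 2.40 TPM with SAHA (adjusted p = 0.280). The 2 lower members were IRF8, which was 1.64-fold lower, and TOX2.

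Genes of cytokine receptors and JAK-STAT signalling rose as a list, with 16 of 25 higher and 3 lower, the same counts adjusted over the list alone (adjusted p = 0.00368; adjusted p = 0.522 with an estimated correlation). IL18R1, a chain of the interleukin 18 receptor, rose 3.25-fold. IL2RA, the alpha chain of the interleukin 2 receptor, was at 21.1 ± 1.45 and 24.2 ± 1.11 TPM (adjusted p = 0.630). The correction for GC content and length called it lower (-0.18 on the log2 scale), with a median of -0.05 over all tested genes. The 3 lower members were IL12RB1, STAT5A and SOCS1. Genes of MHC class II antigen presentation rose as a list, with 6 of 7 tested members higher and RFX5 lower, 6 and 1 adjusted over the list alone (adjusted p = 0.0150; adjusted p = 0.521 with an estimated correlation). HLA-DQB1 rose 3.01-fold, from 6.92 ± 0.431 to 23.7 ± 0.866 TPM, and HLA-DMB, which loads peptides, rose 2.31-fold, with HLA reads as RSEM divided them between close copies. With a stricter filter on low counts this list no longer passed (adjusted p = 0.0945), and 6 of its 12 members had a mean under 1 TPM in both groups. Histone genes that give polyadenylated transcripts outside S phase rose as a list, with 9 of 14 higher and H2AFY lower, or 10 and 1 adjusted over the list alone (adjusted p = 0.0112; adjusted p = 0.522 with an estimated correlation). HIST1H1C, a linker histone gene, rose 1.93-fold and HIST1H2AC 1.59-fold. H1F0, another linker histone gene, is listed at 0 in all 6 libraries.

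The list of MYC and ribosome biogenesis genes fell, with 23 of 24 members lower and none higher, the same counts adjusted over the list alone (adjusted p = 1.57e-10; adjusted p = 0.282 with an estimated correlation). RRP12, a factor in the maturation and export of ribosomal subunits, was 2.70-fold lower, at 55.3 ± 1.66 and 21.9 ± 0.620 TPM, and MRTO4 was 2.21-fold lower. MYC itself was the member that did not pass, at 247 ± 6.85 TPM in the controls and 249 ± 14.9 TPM with SAHA (adjusted p = 0.113, or 0.0225 and lower without SAHA 2). Glycolysis genes fell as a list, with 16 of 20 lower and 2 higher, the same counts adjusted over the list alone (adjusted p = 0.000163; adjusted p = 0.521 with an estimated correlation). HK2, a hexokinase, was 1.87-fold lower and ALDOA, an aldolase, 1.75-fold lower. The 2 higher members were PKM, the muscle-type pyruvate kinase, and PDK1. The list of unfolded protein response, ATF4 target and heat shock genes fell, with 16 of 22 lower and ERN1 higher, 16 and 1 adjusted over the list alone (adjusted p = 0.000163; adjusted p = 0.521 with an estimated correlation). HSPH1, a heat shock protein, was 3.28-fold lower, at 335 ± 6.13 and 109.6 ± 13.5 TPM.

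**Figure D2:**
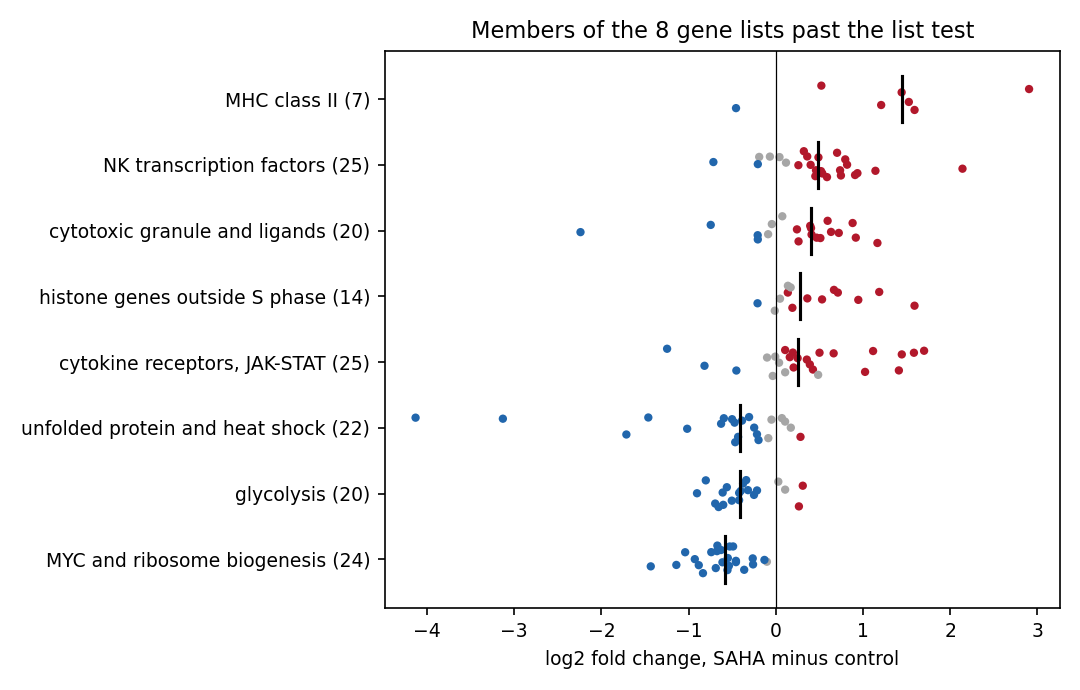
Log2 fold change (SAHA minus control, horizontal axis) of each tested member of the 8 gene lists that passed the list test, with the number of tested members in brackets. Points are genes, red for higher, blue for lower and grey for not past a false discovery rate of 0.05, spread vertically for sight, and the black bar is the median. The median of the MYC and ribosome biogenesis list lies at -0.58 and that of the MHC class II list at 1.44.

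Receptors by which NK cells recognise targets went both ways. Of the activating receptors and adaptors, 9 of 24 rose and 8 fell (list adjusted p = 0.789), the list's median being positive and its test negative in sign. NCR2 and CD160, receptors that trigger NK cells, were 2.16-fold and 1.81-fold lower, and NCR3, another natural cytotoxicity receptor, was 1.45-fold lower, at 498 ± 6.26 and 366 ± 16.3 TPM. KLRK1, which codes for NKG2D, rose 1.26-fold, and CD226 rose 4.80-fold from a low level, 0.170 ± 0.106 to 0.900 ± 0.235 TPM. NCR1 rose 1.14-fold (adjusted p = 0.0160), a call lost without control 1 (adjusted p = 0.0544), without SAHA 2 (0.0728) and in DESeq2 (0.0807). Of the inhibitory receptors, 8 of 15 rose and 3 fell (list adjusted p = 0.329). LILRB1, a receptor of MHC class I, rose 1.83-fold, from 63.4 ± 6.28 to 118 ± 6.28 TPM. The 3 that fell were PVRIG, which was 2.42-fold lower, LAG3 and KLRC1. Of the ligands of NK receptors, NCR3LG1 and MICA rose and CD48, MICB and CLEC2D fell, among 8 tested (list adjusted p = 0.919), a balance that turned to 3 higher and 2 lower with upper-quartile factors and 4 and 1 with library size only.

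Of cytokine and chemokine genes, 6 of 14 rose and 5 fell (list adjusted p = 0.789). IFNG, the interferon gamma gene, rose 1.47-fold, from 26.9 ± 0.757 to 42.6 ± 4.02 TPM, beside IL10 and CCL5. The 5 that fell were LTA, LTB, CCL3, TGFB1 and FLT3LG. Of chemokine receptors and adhesion genes, 12 of 27 rose and 6 fell (list adjusted p = 0.150). ITGA1, an integrin chain that binds collagen, rose 2.74-fold, and NCAM1, the NK marker CD56, rose 2.01-fold, from 89.7 ± 10.05 to 191 ± 9.67 TPM. Among interferon-stimulated genes, 11 of 28 rose and 8 fell (list adjusted p = 0.194). The guanylate-binding protein gene GBP2 rose 2.51-fold and the antiviral gene RSAD2 3.55-fold. Of the MHC class I genes 4 rose, HLA-F, B2M and ERAP1 among them, and 4 fell, PSMB8, PSMB10, TAPBP and ERAP2, out of 15 (list adjusted p = 0.986). With upper-quartile factors 6 rose and 4 fell, and with library size only 9 and 4. B2M, the light chain of MHC class I, rose 1.55-fold and PSMB10, an immunoproteasome subunit, was 1.98-fold lower.

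**Figure D3:**
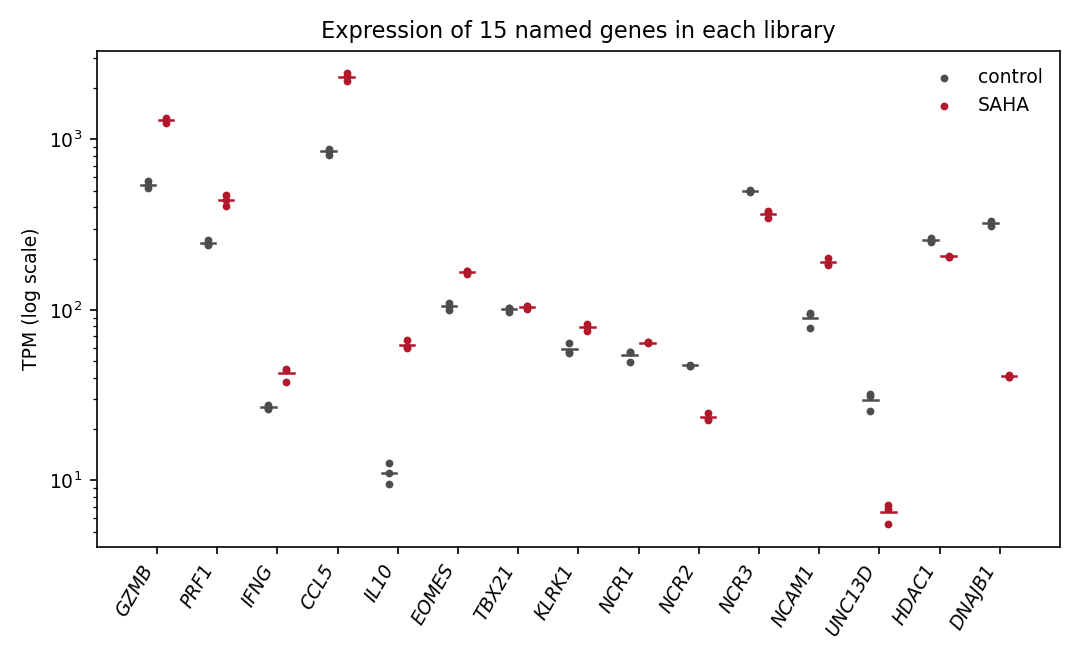
TPM on a log axis of 15 genes in each library, with 3 control libraries (dark grey) and 3 SAHA libraries (red) per gene and a bar at each group's mean. GZMB rises from a mean of 544 to 1293 TPM and DNAJB1 lies at 321 and 40.75 TPM.

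Of the histone deacetylase genes themselves, HDAC4, HDAC5 and HDAC6 rose and HDAC1, HDAC2, HDAC3, HDAC7 and HDAC9 fell, among 10 tested (list adjusted p = 0.646). HDAC9 was 1.86-fold lower and HDAC1 1.38-fold lower, at 256 ± 6.83 and 206 ± 1.496 TPM. HDAC6, a cytoplasmic enzyme that acts on tubulin, rose 1.34-fold. HDAC2 and HDAC3 were 1.14-fold and 1.12-fold lower, and neither passed with scaling to library size only (adjusted p = 0.147 and 0.221) or in the fits of log2 TPM (0.208 and 0.272 with 1 added). HDAC8 was at 21.8 ± 0.620 and 22.8 ± 0.923 TPM (adjusted p = 0.989). The median log2 fold change of this list was -0.08, and 0.01 with library size only. Of acetyltransferase and bromodomain genes, 10 of 22 fell and 5 rose (list adjusted p = 0.547), with a median of -0.05, or 0.04 with library size only, where 6 fell and 7 rose. The correction for GC content and length called this list lower (adjusted p = 0.0374). KAT2A, a histone acetyltransferase, was 2.15-fold lower, and the 5 that rose were BRD3 (1.53-fold), KAT2B, NCOA1, NCOA3 and TAF1. EP300 was at 17.8 ± 2.44 and 19.9 ± 0.357 TPM (adjusted p = 0.529). Of Polycomb and DNA methylation genes, 9 of 23 rose and 9 fell (list adjusted p = 0.870), or 11 and 6 with library size only, PHC1 rising 1.87-fold and TET3 being 1.56-fold lower. Of cohesin, condensin and loop genes, 9 of 25 rose and 6 fell (list adjusted p = 0.580), or 13 and 4 with upper-quartile factors and 14 and 3 with library size only. ESCO2 and ESCO1, which acetylate cohesin, rose 1.82-fold and 1.36-fold, and CTCF was at 48.2 ± 2.09 and 48.6 ± 0.506 TPM (adjusted p = 0.200). The correction for GC content and length called CTCF and EP300 lower, at -0.24 and -0.21 on the log2 scale. The median of all tested genes was -0.05 in that fit, so part of these values is a shift of all genes.

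Genes of the cell cycle also went both ways. Of DNA replication and S phase genes, 16 of 31 fell and 6 rose (list adjusted p = 0.173), or 11 and 10 with library size only. This list was called lower with no filter on low counts (adjusted p = 0.0261) and with the correction for GC content and length (0.0398). CCNE2, a cyclin of the start of S phase, rose 2.25-fold and RRM2, a ribonucleotide reductase subunit, rose 1.49-fold. Of G2 and mitosis genes, 10 of 30 fell and 8 rose (list adjusted p = 0.564), with a median log2 fold change of -0.02 that was 0.03 with upper-quartile scaling (8 fell and 9 rose) and 0.07 with library size only (7 and 12). The correction called it lower (adjusted p = 0.0250). UBE2C and AURKA, which act in mitosis, were 1.61-fold and 1.58-fold lower. The proliferation marker MKI67 rose 1.14-fold (adjusted p = 0.0248), a call lost without control 1 (adjusted p = 0.0810), control 2 (0.0737) or SAHA 3 (0.135), and it lay at -0.08 on the log2 scale after the correction for GC content and length. Of CDK inhibitor, G1 cyclin and growth arrest genes, 9 of 16 rose and 4 fell (list adjusted p = 0.136, or 0.0220 and higher with no filter on low counts). CDKN2D, an inhibitor of CDK4 and CDK6, rose 3.87-fold, from 13.1 ± 1.03 to 55.4 ± 5.34 TPM. The 4 that fell were CDK4, 1.52-fold lower, CCND2, CCND3 and GADD45B. CDKN1A, the gene of p21, had too few reads to be tested, at 0.243 ± 0.0451 TPM in the controls and 0.117 ± 0.0404 TPM with SAHA. Of homologous recombination and Fanconi anaemia genes, 6 of 26 rose and 6 fell (list adjusted p = 0.950), or 8 and 5 with library size only, with ATM rising 1.44-fold and NBN being 1.44-fold lower.

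Of pro-apoptotic genes, 10 of 22 rose and 7 fell (list adjusted p = 0.580). APAF1, the scaffold of the apoptosome, rose 2.17-fold and BID was 2.12-fold lower. Of the 10 tested anti-apoptotic genes, CFLAR (1.76-fold), MCL1 (1.64-fold), BIRC2, BIRC3 and BCL2 rose, and BCL2L1, XIAP, BAG1 and BAG3 fell (list adjusted p = 0.564). Of cholesterol synthesis and uptake genes, 13 of 21 fell (list adjusted p = 0.0606, or 0.00910 and lower with no filter and 0.0285 with the correction), HMGCS1 being 1.64-fold and FDFT1 1.58-fold lower, and SC5D, SREBF1, ABCG1 and MYLIP were among the 5 that rose. Of metallothionein and redox genes, 8 of 18 fell and 6 rose (list adjusted p = 0.580), with GPX1 2.14-fold lower and MT2A 2.02-fold higher. Of the neuronal genes, SNAP25, SYP, SYT11 and VGF rose and SYT1 fell, among 8 tested (list adjusted p = 0.474), and 21 of the 28 members had a mean under 1 TPM. For the lists that did not pass, the counts adjusted over the list alone were the same, except for CDK inhibitor genes (9 and 5), inhibitory receptors (8 and 4), neuronal genes (4 and 2), metallothionein and redox genes (7 and 9), mitochondrial genes (2 and 0) and cytokines (7 and 5).

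Markers of other cells and of RNA quality were tested in the same way. Of genes of the mitochondrial DNA, MT-CYB (1.24-fold), MT-ND3 (1.14-fold) and MT-CO2 rose and none of the 13 fell (list adjusted p = 0.613), and the correction for GC content and length ended the calls of MT-CYB (adjusted p = 0.0935) and MT-ND3 (0.301). Of T cell markers, TRDC, CD3E, TRAC, CD8B and CD40LG fell and CD28 and THEMIS rose, among 11 tested (list adjusted p = 0.539), TRDC being 1.94-fold lower and CD28 1.62-fold higher. Of B cell markers, IGJ was 1.63-fold lower, at 173 ± 8.39 and 111 ± 0.513 TPM, and MS4A1, at 0.313 ± 0.117 and 1.03 ± 0.359 TPM, and TNFRSF13C rose, among 5 tested (list adjusted p = 0.950). Lists of myeloid, erythroid and megakaryocyte, and epithelial and stromal markers had fewer than 5 tested members and no list test. Their tested members were MNDA, at 0 TPM in the controls and 0.613 ± 0.1002 TPM with SAHA, EPOR, which was 1.31-fold lower, FN1, which rose 1.30-fold, and VIM, which rose 1.09-fold (adjusted p = 0.0351). The EPOR call was lost without SAHA 3 (adjusted p = 0.0583), in DESeq2 (0.0592), in the fits of log2 TPM with 1 or 0.1 added (0.203 and 0.208) and with the correction for GC content and length (0.0723). That of VIM was lost without control 2 (0.116), control 3 (0.156), SAHA 1 (0.145) or SAHA 2 (0.129), with the replicate block (0.0548), with RLE factors (0.0501) and with no filter on low counts (0.103).

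The direction of the changes differed with expression level. In the quartile of lowest mean expression, 69.1% of the called genes were higher with SAHA (95% exact binomial interval 66.5 to 71.6, which treats genes as independent), and in the next quartile 64.7% (62.7 to 66.7). In the third it was 47.2% (45.2 to 49.2), and in the quartile of highest expression 32.5% (30.6 to 34.3). The third quartile turned with the scaling, to 53.8% with upper-quartile factors and 59.2% with library size only. Direction also ran with GC content and gene length, looked at after seeing the data. In 5 bins from low to high GC content, 63.5%, 57.5%, 51.8%, 44.8% and 35.5% of the called genes were higher. From short to long genes it was 41.0%, 42.0%, 47.5%, 55.1% and 65.1%. The quartiles were not recomputed with the correction for GC content and length, so expression level was not separated from these. Genes detected in 1 group alone, at 1 TPM or more in its 3 libraries and under 0.1 TPM in the other 3, were few. They were ENSG00000263011.1 (sense overlapping) and ENSG00000253593.2 (long intergenic noncoding) with SAHA, with 12 and 28 reads in total, and ENSG00000271196.1 (a processed pseudogene) in the controls, with 3 reads. Without SAHA 1, 11 genes met this rule for SAHA, and without control 1, 7 met it for the controls.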

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

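The correction for GC content and gene length was the only alternative chosen after seeing the data. The number of called genes lay between 6956 and 9044 over the other scalings, filters, units and tools and the correction, and between 7699 and 8066 with 1 library left out. It was 6883 at a false discovery rate of 0.01 and 1553 against a fold change of 1.5, both stricter by construction. Of the genes called both in the reported test and in an alternative, none had the opposite sign, except 2 in each fit of log2 TPM and 5 with the correction for GC content and length. With the replicate block, as if the numbers were paired, 8453 genes were called, 8284 of them also called without it. The libraries of equal number correlated by -0.02, 0.03 and -0.02 in their deviations from the group means, across genes, which are not independent replicates, and 2 of 6 libraries were closest to the library of their own number. Of the 96 tested genes that the rule for named genes took, 59 kept their direction and side of the threshold in every alternative that tested them (the stricter filter did not test CD226, IGHV1OR15-1, MNDA and MS4A1), and 30 lost the call against a fold change of 1.5. SAHA 1 had the lowest total, 18675093 counts, and genes with few reads, such as CD226, MS4A1 and those detected in 1 group alone, rest on counts that allow no fine estimate.

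Genes at least 2-fold higher and lower were 354 and 169 with the stricter filter, which tested 10145 genes, and 388 and 133 with limma-trend on log2(TPM + 1). Genes lower were 2549 with that fit and 2550 with 0.1 added. TPM values carry no TMM factor, and the median log2 fold change was 0.099 and 0.12 in these fits. It was 0.11 with library size only, where 3219 genes were lower. A shift of scale thus goes with part of the drop, and the cause of the rest was not tested. Against a fold change of 1.5, 939 were higher and 614 lower. The percent higher by quartile, from low to high expression, was 72.6, 69.7, 53.8 and 39.8 with upper-quartile factors, and 76.1, 73.5, 59.2 and 46.5 with library size only, so that the third quartile turned. Another scaling by construction shifts all log2 fold changes by about the same amount, which moves genes across 0. With quartiles of log2 TPM the second was 69.0 and the fourth 27.0. Genes detected in 1 group alone were 1 for SAHA and 0 for the controls at 5 TPM against under 0.5. For SAHA they were 10, 5 and 9 without control 1, 2 and 3, and 11, 7 and 5 without SAHA 1, 2 and 3. For the controls they were 7, 5 and 5, and 2, 4 and 4, in the same order. Leaving out a library by construction loosens the rule. Detected genes differed by 534 at 0.1 TPM (exact permutation p = 0.1) and by 296.67 at 10 counts (exact permutation p = 0.4).

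Lists called lower were 5 with no filter, 7 with the correction for GC content and length, 0 with an estimated correlation and 11 with fry, and lists called higher were 0 with an estimated correlation and 13 with fry. Lists that gained a call as lower were S phase with no filter (adjusted p = 0.0261) and the correction (0.0398), over a range of 0.0261 to 0.488 in all alternatives of this test, and with the correction G2 and mitosis (0.0250; 0.0250 to 0.879) and acetyltransferases (0.0374; 0.0374 to 0.744). CDK inhibitors gained one as higher with no filter (0.0220; 0.0220 to 0.140). The cholesterol list passed with no filter (0.00910), the correction (0.0285), without control 3 (0.0480) and without SAHA 1 (0.0417), over a range of 0.00910 to 0.154. With library size only, members higher and lower were 14 and 5 for interferon-stimulated genes, 15 and 3 for chemokine receptors and adhesion, 3 and 3 for histone deacetylases, 14 and 2 for cytotoxic genes, 21 and 1 for NK transcription factors and 5 and 0 for mitochondrial genes. Lists whose direction turned did not pass in either form. For MHC class I the adjusted p was 0.981 with RLE factors, 0.832 with no filter, 0.907 with the replicate block and 0.683 to 0.922 with 1 library left out, where the direction turned without control 2, control 3, SAHA 1 or SAHA 2 (0.860 to 0.922). For homologous recombination it was 0.945 with no filter, 0.273 with the correction and 0.775 to 0.894 with 1 library left out, where the direction turned without control 1 (0.894) or SAHA 3 (0.810). B cell markers turned with no filter (0.992) and the correction (0.975), ligands of NK receptors with the stricter filter (0.879) and fry (0.977), and loop genes (0.273) and activating receptors (0.988) with the correction. The causes were not tested.

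Some log2 fold changes turned. With upper-quartile factors they were 0.050 for HDAC8 and 0.016 for IL2RA. With library size only they were 0.094 for HDAC8, 0.026 for TBX21, 0.059 for IL2RA and 0.023 for CTCF. With the stricter filter HDAC8 was at 0.026. On log2(TPM + 1) they were 0.059 for HDAC8, 0.050 for TBX21, 0.195 for IL2RA, 0.0082 for MYC and 0.014 for CTCF, and on log2(TPM + 0.1) 0.061, 0.051, 0.203, 0.0082 and 0.014. With the correction for GC content and length TBX21 was at 0.0095, MKI67 at -0.084 and EP300 at -0.21, the last with an adjusted p of 0.00117. The correction also called CTCF (-0.24) and IL2RA (-0.18) lower and ended the calls of MT-CYB (adjusted p = 0.0935), MT-ND3 (0.301) and EPOR (0.0723). The replicate block ended that of VIM (0.12, adjusted p = 0.0548). With 1 library left out HDAC8 lay between -0.018 and 0.018, IL2RA between -0.068 and 0.00099 and EP300 between -0.035 and 0.12. MYC was called lower without SAHA 2 (-0.16, adjusted p = 0.0225). Beyond the shift of the median that other scalings, TPM and the correction bring, the causes were not tested.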

Other observations

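The families and sets of this part were chosen by name after the results above were seen, and so were the tests of immediate early genes, of CD74 and of genomic DNA spread evenly. In SAHA-treated NK92 cells, 7 of 14 gene families and sets tested beyond the lists fixed in advance were called lower. The test compared each family with all other tested genes, not with genes of like expression. In the quartile of highest mean log2 TPM, 1881 of 3518 genes fell and 697 rose. Of mitochondrial ribosomal protein genes 65 of 76 fell and 3 rose, of proteasome subunit genes 34 of 37 fell and none rose, and of aminoacyl-tRNA synthetase genes 28 of 35 fell and 1 rose. All 8 genes of the TRiC chaperonin fell, as did 29 of 39 translation initiation factors and 25 of 35 subunits of respiratory complex I, with 1 member higher in each of the last. With limma camera the adjusted p was 8.84e-14, 1.54e-12, 2.94e-08, 1.74e-06, 6.73e-08 and 2.77e-05 in this order. With an estimated correlation it was 0.259, 0.259, 0.0356, 0.259, 0.117 and 0.404, so that of these 6 the synthetases alone passed. Their median log2 fold changes were -0.46, -0.44, -0.37, -0.68, -0.33 and -0.30, and with library size only 60, 33, 26, 8, 24 and 22 members fell.

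Of cytosolic ribosomal protein genes 36 of 85 fell and 3 rose, or 13 and 10 with library size only (adjusted p = 0.00409; adjusted p = 0.689 with an estimated correlation). The share that fell was below that of all genes in the quartile of highest log2 TPM (1881 of 3518). The call thus does not set this family apart from other abundant genes. Of zinc finger genes named ZNF, 146 of 332 rose and 57 fell (adjusted p = 0.00716; adjusted p = 0.353 with an estimated correlation), or 176 and 36 with library size only and 122 and 86 after the correction for GC content and length. Of Kruppel-like factors 5 of 7 rose and 1 fell (adjusted p = 0.0213; adjusted p = 0.259 with an estimated correlation). Long intergenic noncoding RNA held 0.360 ± 0.00473% of the counts in the controls and 0.636 ± 0.0336% with SAHA (SD, n = 3 per group; exact permutation p = 0.1), and 0.262 ± 0.00197% and 0.298 ± 0.00961% without NEAT1 and MALAT1. NEAT1, the RNA scaffold of paraspeckles, rose by 1.91 on the log2 scale, from 349 ± 15.2 to 1524 ± 120 TPM.

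Of a wider set of heat shock genes, not tested for enrichment, 24 of 28 tested members were lower and 2 higher, with a median log2 fold change of -1.07. They held 1.34% to 1.44% of the counts in the controls and 0.633% to 0.689% with SAHA. The set's median was -1.11 after a correction of each library for GC content and length, and its highest value under 3 other scalings was -0.97, which argues against both as the cause. Stress from handling in the control cultures may raise heat shock genes and cannot be told apart from an effect of SAHA, since the share of the 13 called immediate early genes that were higher with SAHA, 76.9%, has a 95% exact binomial interval of 46.19 to 94.96 and SAHA could raise these genes itself. As a set they were called higher (adjusted p = 0.0460, and 0.00933 after the correction), against what such stress would give, but not with an estimated correlation (adjusted p = 0.545).

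Constant region genes of immunoglobulin heavy chains were lower with SAHA, all 5 tested genes falling. The variable segment IGHV1OR15-1 went the other way and rose 5.50-fold. B or plasma cells among the untreated cells would bring light chains as well. The 6 light chain genes searched stood in the controls at 0% of the level of IGHM (120.5 TPM), which does not decide the question. IGLC3 had reads in SAHA 2 alone (a group mean of 0.0667 ± 0.115 TPM with SAHA). Its model can thus take reads, though this rests on that library and a value near the floor. Its 0 in the controls says nothing of cells that use another light chain. The others searched, IGKC among them, were at 0 in all 6 libraries. So were CD7, an NK gene, and H1F0, which could come from the gene models. B cells are argued against by CD74, an abundant transcript of theirs, which had reads in every library and stood in the controls at 0.105% of the level of IGHM (0.127 ± 0.0603 TPM). Plasma cells also express IGJ, the joining chain gene, which was at 173 ± 8.39 TPM in the controls and 1.63-fold lower with SAHA. IGHM was 6.50-fold lower, and these unequal falls argue against a loss of plasma cells as the source of both genes. As a source of the heavy chains alone, plasma cells cannot be told apart from a change in NK92 itself. After the correction for GC content and length the median of the 5 genes was -1.97, against -2.12 before it, which argues against GC content or length as the cause.

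Among changes of at least 2-fold, 68.6% were higher with SAHA, 72.8% and 76.5% in the 2 quartiles of lower expression, but 47.1% (95% exact binomial interval 37.8 to 56.4; 52.8% with quartiles of log2 TPM) in the third and 37.6% (27.8 to 48.3) in the highest. The share was 64.8% after the correction for GC content and length, and 60.5% among genes past a test against a fold change of 1.5 (95% exact binomial interval 58.0 to 62.9), which argues against GC content or length and against counting noise as the whole cause. The summed CPM of 399 olfactory receptor genes was 2.34 times higher with SAHA, which might come from genomic DNA or unspliced RNA, but OR4C6 held 96.8% of this rise and the ratio was 1.14 without it (1.36 ± 0.293 and 1.55 ± 0.270 CPM). The ratio of 2.34 met the mark of at least 1.5 that was set beforehand for such a source. That mark did not foresee 1 gene setting the sum. With OR4C6 doing so, genomic DNA or unspliced RNA cannot be told apart from a change of that gene. DNA spread evenly over the genome is argued against by the median rise of the genes at least 2-fold higher, 1.01 CPM per kilobase, which was 512 times the upper 95% limit for the other olfactory receptor genes.

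The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with as large a result, 1 of 10 here, cannot be under 0.1. The real split called 8420 genes and the highest of the other splits 0. Each of the other splits has control and SAHA libraries on either side. The difference between treatments then adds to the spread within a side, which by construction lowers the number of genes called. The 0 is thus no measure of what libraries without a treatment effect would give, and its contrast with 8420 does not decide the question of chance. For the fixed lists the real split called 8 and the highest of the other splits 5, which comes from the same mixed splits and does not decide it either.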
